A study of Mus musculus with 12 samples.

How the data were processed

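Total RNA of 12 mouse samples was measured on 2-colour spotted arrays, with the sample in Cy3 and embryonic reference RNA in Cy5 per the labels. The deposited values are read here as log2 ratios between the channels. The base is inferred from their range of -14.6 to 18.2, since the unit is not given in the sources used here. The authors describe a Lowess fit of the log ratio on log intensity over 50% of the data and a floor of 200 for the control channel. The deposited values are not centred, with array medians from -1.24 to 0.893. The highest log2 ratio a 16-bit scanner gives over that floor is 8.36. With the sample as the floored channel, 38 to 326 values per array lay beyond it, and with the reference as the floored channel 0 to 82 did, with 0 on 1 array, so under either reading the floor does not bound the deposited values. The scanner, the image software and the background method are not given in the sources used here. Which channel is the numerator is not stated either. The design fixed before the data were examined assumed sample over reference. A check fixed at the same time showed the opposite, with 37 of 42 embryo-tissue genes on the reference side and a median of -4.26 after the sign was turned, and between 77.8% and 91.9% of them on that side of the median on each array. All values were therefore multiplied by -1.

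Of 23040 spots, 902 controls were left out (573 blank, 235 Gapdh and 94 YIR spots). Of the 22138 others, 11245 had a value on all 12 arrays and were kept. Spots of one gene were averaged, which gave 10762 features, 8707 named genes and 2055 unnamed spots. Of 367 genes with several spots, 179 had spots that differed in the sign of NLS minus WT. Gene symbols were checked against RefSeq genes by Entrez identifier (16249 spots matched, 0 symbols updated). No genome positions were used. Per array, 12.5% to 29.2% of spots had no value and 7.85% to 19.6% of blank spots had one. Arrays of one group correlated at 0.337 to 0.634 across genes, which are not independent replicates. The median was 0.432, against 0.417 for arrays that differed in both group and letter. For different groups of one letter it was 0.536, so arrays of a letter were more alike than arrays of a group.

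Groups were WT 0GH, WT 1GH, NLS 0GH and NLS 1GH with 3 arrays each. Each comparison was fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 on all 12 arrays, two-sided, with Benjamini-Hochberg adjustment within the comparison and a threshold of 0.05. The 6 comparisons, their test and the gene lists were chosen before the data were examined. A 7th, the receptor difference averaged over both GH numbers, was added after they were seen. The fit uses neither centring nor a block, as chosen in advance. Since centring moves the median by over 0.1, gene and list differences are given relative to the median difference of all genes in that comparison (the median shift), and SE is that of the limma fit. The p-values of single genes in that fit are those of the differences before this subtraction. Centred values have the median of the tested features of their array subtracted. The levels of marker and embryo-tissue genes are instead relative to the median of all spots of the array with a value, controls left out.

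Samples of one letter share the same red dye incorporation in the labels (19.3, 19.8 and 17.9 bp per dye molecule for b, c and d), so they share a labelling of the reference, and the letter was treated as a block in an alternative fit. As a check of this pairing, deviations from group means correlated across genes between 0.0433 and 0.263 within a letter and between -0.187 and 0.066 between letters. The exact permutation test reassigns arrays within each letter (216 assignments, smallest possible p 0.00926) on the list mean of centred values, and was added after the data were seen.

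The 25 gene lists cover GH and STAT5 targets, JAK-STAT components, immediate early, DNA replication, G2/M, apoptosis, ribosome biogenesis, ribosomal protein, nuclear transport, adhesion, glycolysis, oxidative phosphorylation, cholesterol synthesis, heat shock, interferon and p53 genes, markers of 8 cell types and the embryo-tissue genes. Each list with at least 5 measured genes was tested with limma's camera at a preset correlation of 0.01, adjusted over 150 pairs of list and comparison (5 passed), and separately over the 25 lists for the added comparison (5 passed). The named genes are those past the threshold with the same sign in all letters, or, where fewer than 5 pass, the 5 with the smallest p in each direction, given as values, together with genes fixed in advance such as Ghr, Cish, Socs2, Pim1, Id1, Birc5, Mybbp1a and Fxyd5. Examples from a list are not changes that passed on their own.

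Alternatives planned in advance were the replicate block as fixed or random, centring, quantile normalization, at least 2 values per group, the outer 5% of ratios left out at each end, spots not averaged, a robust prior, green dye incorporation as a covariate, a fold of at least 1.5, the compared groups only, leaving out each array or letter, and an estimated correlation for lists. Centring together with the block, with and without array weights, was added later. The tests were also run on simulated data, in 5 runs. Values were normal and independent between features, with the mean and residual spread of each feature in the fit with centring and the block. A random shift for each feature and letter was added, and the real median of each array was put back. Changes of each size were added to 250 features over the runs. In the NLS 0GH against WT 0GH comparison the fit recovered 0% of added log2 changes of 2, 1.6% of 3 and 47.2% of 5, and with centring and the block 19.2%, 36% and 61.2%. Calls among all other features, the shifted list included, came to 3 over the 5 runs, and to 21 with centring and the block. A shift of 0.5 added to a list was called in 4 of 5 runs in the averaged comparison and in 1 of 5 at 0GH.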

Results

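Transcript levels were compared in 12 mouse samples on spotted arrays, each hybridised with a Cy3-labelled sample and a Cy5-labelled reference made from embryonic RNA. The series title names the nuclear growth hormone receptor. The sample titles set a form called WT (wild type) beside a form called NLS, the usual abbreviation for a nuclear localization signal, each with a 0 or a 1 before GH (growth hormone). This gives 4 groups, WT 0GH, WT 1GH, NLS 0GH and NLS 1GH, of 3 arrays each, with replicate letters b, c and d. All titles also carry a 10 after the receptor name, whose meaning the labels do not give. Human growth hormone at 100 ng/ml is listed for all samples and the series is described as a time course, but the titles give no unit for the 0 and the 1, so the values are reported by those numbers and not as hours or as treated and untreated. The labels name neither the cell type nor whether the letters are separate cultures, so the tests measure the spread between these samples and no more. Between 15939 and 19700 of 23040 spots had a value on an array, and 8707 named genes and 2055 unnamed spots had a value on all 12. The small number of arrays limits the precision of every value.

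Some genes of blood cells lay high in these samples, while most marker lists of blood cells did not. Relative to the median of each array, the log2 ratio was 3.88 for Cd79b (SD 1.37 over 10 arrays) and 2.90 for Cd79a (SD 1.21), which encode the signalling chains of the B cell receptor. It was 3.74 for Prtn3 (SD 1.49), a granule protease of myeloid cells, 3.03 for Dntt (SD 1.0), the template-independent polymerase of lymphoid precursors, and 2.80 for Gata2 (SD 0.74), a haematopoietic transcription factor. Genes of connective tissue lay low, with Col5a2 at -10.57 on 9 arrays and Col2a1 at -7.21. Both belong to the embryo-tissue genes that set the sign of all values, so their side is not an independent result. The size for Col5a2 lies beyond the 8.36 that a 16-bit scanner gives over the named floor, so it is not an exact level. As a list, the erythroid and megakaryocyte markers had a median of 1.07, the B lymphoid markers 0.05, the mast cell and basophil markers -0.19, the T lymphoid markers -0.83, the myeloid markers -1.10, the fibroblast markers -3.52, the epithelial markers -3.55 and the hepatocyte markers -4.47. The fibroblast, epithelial and hepatocyte lists share members with the embryo-tissue genes, so their low side is not independent of the choice of sign. All these levels are against an embryonic reference and not absolute. Ghr, the growth hormone receptor gene, lay at 0.42 (SD 1.07 over 12 arrays), and Cish, a feedback inhibitor induced through STAT5, at 2.07 (SD 0.90). The median here is that of all spots with a value, so these levels differ from the centred values given below, which use the tested features. The labels do not say which channel is the numerator. Of 42 embryo-tissue genes chosen for this check before the data were examined, 37 lay on the reference side of the array median when the deposited values were read as reference over sample, and all signs here follow that reading. The opposite reading would turn every sign in the text.

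The comparison of NLS with WT at 0GH asks how the transcripts differ between the receptor forms at the lower GH number. Genes of ribosome biogenesis and the nucleolus were higher in NLS arrays. Of 29 measured genes, 24 lay above the median shift of all genes, and the list mean was 0.75 log2 units above that shift. Mybbp1a, a nucleolar protein that binds the transcription factor Myb, was at 1.45 (SE 0.67), Nhp2, a protein of small nucleolar ribonucleoprotein particles, at 1.34 (SE 0.64), Ddx18, an RNA helicase, at 2.27 (SE 1.02), and Nip7, needed for ribosome assembly, at 2.59 (SE 1.05). Genes of glycolysis were higher by 0.68, with 14 of 18 above the shift, among them Pgam1 at 2.97 (SE 0.92), Ldha at 1.60 (SE 0.80) and Tpi1 at 2.17 (SE 1.43). Ribosomal protein genes were higher by 0.34, with 47 of 54 above the shift, including Rps12 at 1.14 (SE 0.66) and Rpl9 at 0.88 (SE 0.54). The adjusted p from limma's camera test was 0.0013 for ribosome biogenesis, 0.0434 for glycolysis and 0.0434 for ribosomal protein genes. With an inter-gene correlation estimated from the data instead of the preset one, the adjusted p was 0.997 for each of the 3 lists. Without centring, that estimate includes shifts that all genes of an array share. For the immediate early genes it was 0.449, and -0.0054 with centring and the block. In that centred fit the adjusted p with an estimated correlation was 0.693 for ribosome biogenesis and glycolysis and 0.882 for ribosomal protein genes. The calls therefore rest on the preset correlation.

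By replicate letter, the centred list mean of NLS 0GH minus WT 0GH was 0.92 in b, 1.03 in c and 0.28 in d for ribosome biogenesis, and 0.27, 0.59 and 1.17 for glycolysis. With the letter as a block, the adjusted p was 0.000957 for ribosome biogenesis, 0.00409 for glycolysis and 0.0112 for ribosomal protein genes. Without the block and without letter b, c or d in turn, it was 0.0522, 0.137 and 0.0015 for ribosome biogenesis, 0.0259, 0.137 and 0.636 for glycolysis, and 0.102, 0.329 and 0.316 for ribosomal protein genes. Genes of oxidative phosphorylation had a list mean of 0.39 and an adjusted p of 0.0536, which became 0.0238 with the block and was 0.997 with an estimated correlation. No single gene passed the threshold in limma (0 of 10762). An unadjusted p under 0.05 was found for 239, of which 41 were higher, so most had the sign of the median shift. Evenly spread p-values would give 538, and other splits of these arrays gave 158 to 2238. With each array centred and the letter as a block, 0 passed and 750 had an unadjusted p under 0.05. The median shift of this comparison was -0.18. Beyond the genes above, the smallest p-values among higher genes belonged to Rtca at 5.49 (SE 1.28), Gbp2 at 3.81 (SE 0.94), an interferon-induced GTPase, Phgdh at 2.52 (SE 0.71), the first enzyme of serine synthesis, and Clpb at 3.98 (SE 1.24). Among lower genes they belonged to Sulf2 at -5.35 (SE 1.27), a sulfatase of heparan sulfate, Tcte1 at -4.73 (SE 1.20), Zkscan6 at -2.81 (SE 0.78), Kremen2 at -4.40 (SE 1.21) and Rabif at -2.81 (SE 0.79).

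At 1GH the same question was put to the other 6 arrays. Genes of ribosome biogenesis were again higher in NLS arrays, by 0.56, with 21 of 29 above the shift (camera adjusted p = 0.0197, or 0.0134 with the letter as a block). With an estimated correlation the adjusted p was 0.997. The means by letter were 0.63, 0.50 and 0.41, and the adjusted p was 0.4002 without letter b, 0.137 without c and 0.0183 without d. Nip7 was at 3.28 (SE 1.05), Bysl, a factor of small-subunit assembly, at 2.47 (SE 1.02) and Ebna1bp2 at 2.96 (SE 1.25). Genes of nuclear import and export had a list mean of 0.60, with 16 of 24 above the shift, and an adjusted p of 0.05004 that did not pass, against 0.0086 with the block and 0.997 with an estimated correlation. Ribosomal protein genes had a mean of -0.26, with 40 of 54 below the shift, and an adjusted p of 0.767 (0.0278 with centring and the block, 0.893 with an estimated correlation added). Before subtraction of the shift that mean was 0.09, so its sign depends on the scaling. No gene passed in limma (0 of 10762), and 234 had an unadjusted p under 0.05 (565 with centring and the block), at a median shift of 0.35. Of the 234, 215 were higher, the sign of the shift. The smallest p-values belonged to Psmd7, a proteasome subunit, at 4.22 (SE 0.88), 4930526I15Rik at 4.70 (SE 1.0), 4930533K18Rik at 3.90 (SE 0.93), Col8a1 at 3.08 (SE 0.84) and Cacul1 at 6.53 (SE 1.73) among higher genes, and to Cenpu, a centromere protein, at -4.20 (SE 1.20), Snhg6 at -4.18 (SE 1.28), F11r at -3.77 (SE 1.21), Ramp2 at -2.60 (SE 0.81) and Cp at -2.58 (SE 0.83) among lower ones.

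Averaging the receptor difference over both GH numbers uses all 12 arrays. This comparison was added after the data were seen. In it, 5 lists were higher in NLS arrays by camera with the preset correlation. With an estimated correlation each of the 5 had an adjusted p of 0.991, or 0.119 to 0.218 with centring and the block. Ribosome biogenesis was higher by 0.66 (24 of 29 genes above the shift, adjusted p = 4.17e-06). Oxidative phosphorylation was higher by 0.32 (30 of 38 genes, adjusted p = 0.00198), with Ndufs4 at 1.41 (SE 0.60) and Sdhc at 0.88 (SE 0.42). Glycolysis was higher by 0.56 (13 of 18 genes, adjusted p = 0.00317), with Ldha at 1.33 (SE 0.56) and Slc2a3, a glucose transporter, at 1.25 (SE 0.63). Nuclear import and export was higher by 0.46 (16 of 24 genes, adjusted p = 0.00377), with Nup93, a nuclear pore protein, at 1.16 (SE 0.45) and Kpna6, an importin, at 2.01 (SE 0.79). Cholesterol and lipid synthesis was higher by 0.60 (10 of 17 genes, adjusted p = 0.00377), with Scd2, a fatty acid desaturase, at 1.36 (SE 0.41) and Idi1 at 1.80 (SE 0.87). All 5 differences had the same sign in each of the 3 letters. Without letter b the adjusted p was 0.145 for nuclear import and export and for oxidative phosphorylation, and without letter c it was 0.0628 for cholesterol synthesis.

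An exact two-sided permutation of the labels within letters gave p = 0.00926 for each of these 5 lists, the smallest value that its 216 assignments can give, and an adjusted p of 0.0331 over the 25 lists. The JAK-STAT list, which includes Ghr itself and was drawn up with members that serve other cytokine receptors, reached the same exact p. Its centred mean was 0.38, and it did not pass the camera threshold (adjusted p = 0.335). Of its 14 genes 7 lay above the shift and 7 below, with a centred median of 0.12, so the mean rests on some of them. Erythroid and megakaryocyte markers had a mean of -0.47, with 7 of 8 below the shift, and the same exact p. Their camera adjusted p was 0.154, which became 0.0382 with the block. With an estimated correlation the adjusted p was 0.991, or 0.176 with centring and the block. Hba-a1, an alpha globin, was at -1.35 (SE 0.69) and Gata1, an erythroid transcription factor, at -0.88 (SE 0.61). The Gapdh control spots lay higher in NLS than in WT arrays in 4 of 6 pairs of the same letter and GH number and lower in the other 2, which was not tested.

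**Figure D1:**
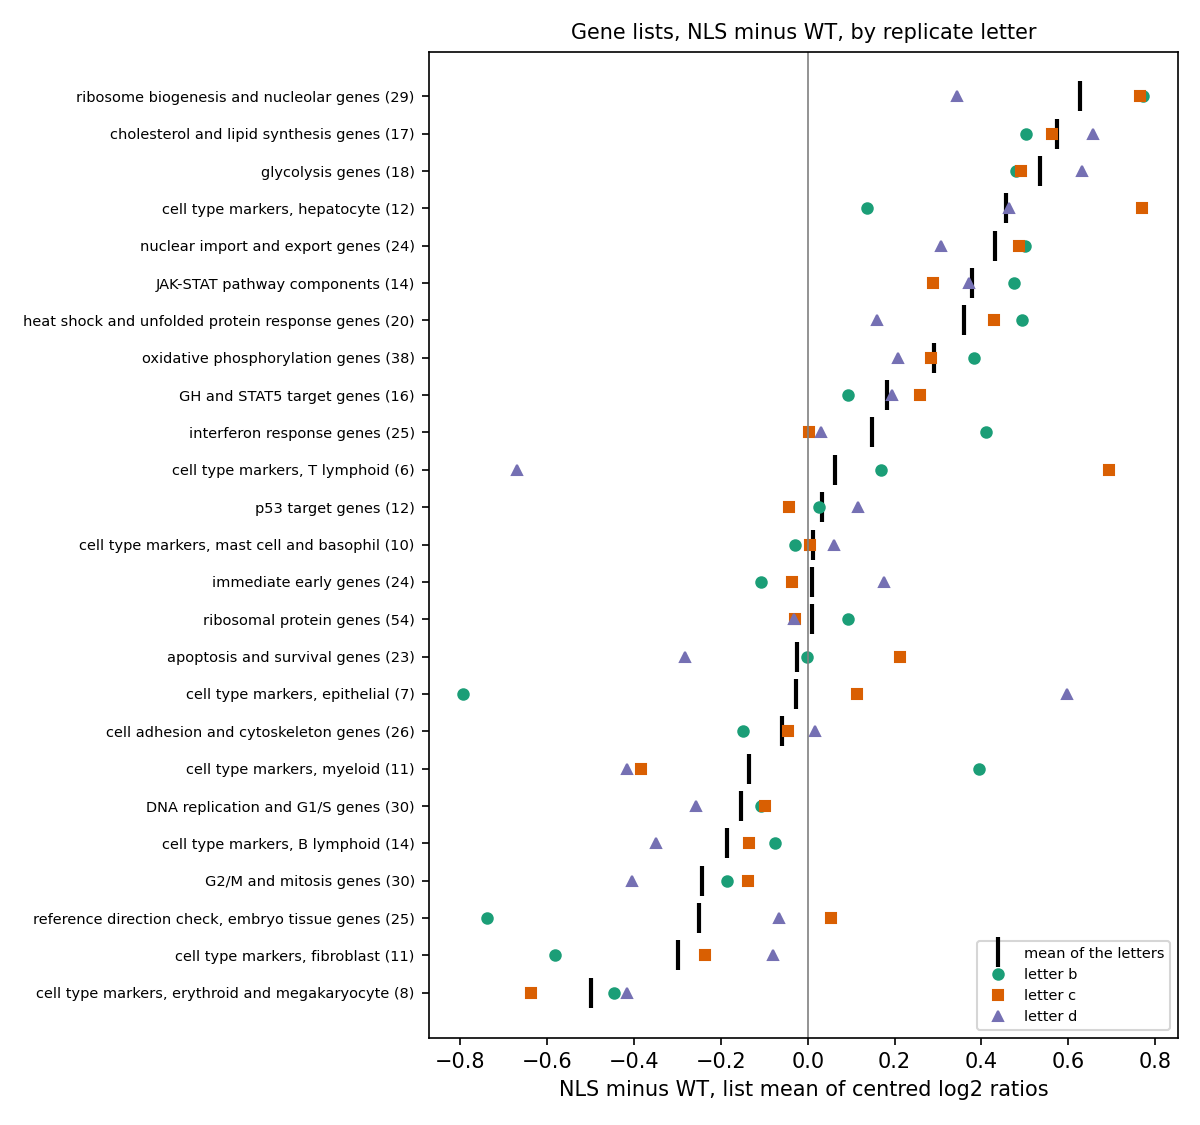
Mean log2 difference between NLS and WT arrays for each gene list, relative to the median of all genes, averaged over both GH numbers and within each replicate letter. Ribosome biogenesis lies at 0.77 in b, 0.77 in c and 0.34 in d.

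**Figure D2:**
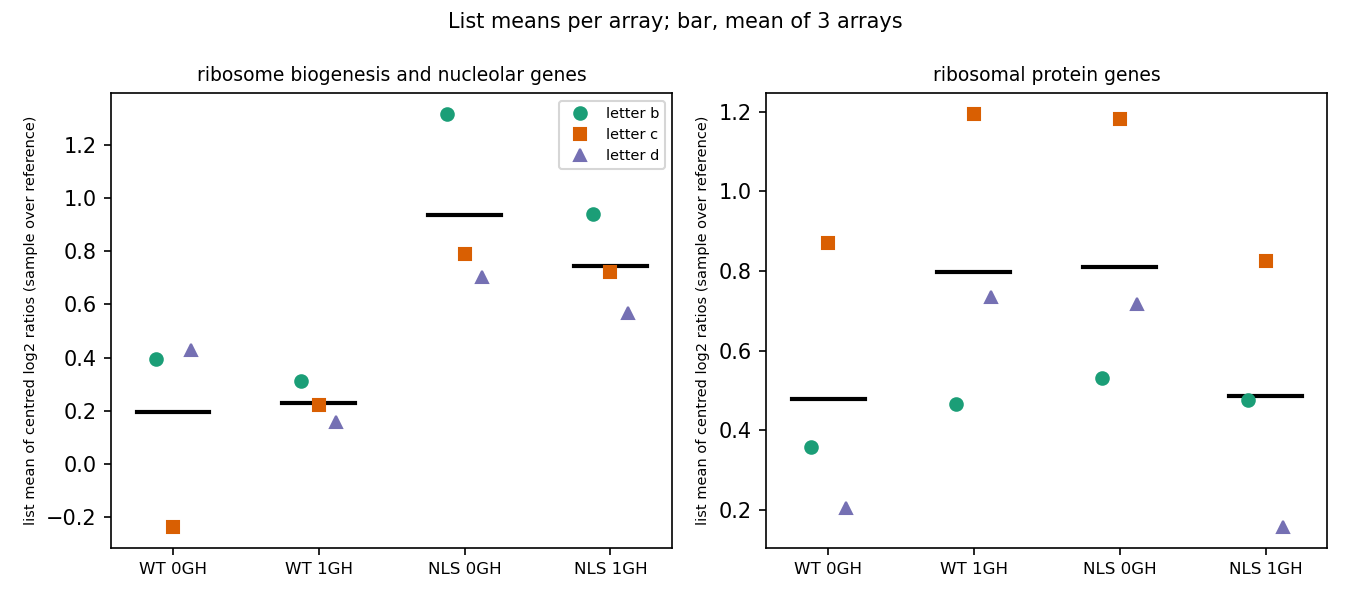
Mean centred log2 ratio of gene lists on each of the 12 arrays, by receptor form, GH number and replicate letter. For ribosome biogenesis the 6 NLS arrays lie between 0.57 and 1.32 and the 6 WT arrays between -0.24 and 0.43.

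Among single genes of the averaged comparison, the smallest p-values on the higher side belonged to 5 genes. Relative to the median shift of 0.08, Phgdh was at 2.24 (SE 0.50), Nip7 at 2.94 (SE 0.74), Eif5a, a translation factor, at 1.68 (SE 0.46), Pgam1, a glycolytic mutase, at 2.40 (SE 0.65) and Gbp2 at 2.40 (SE 0.66). On the lower side were Sulf2 at -4.42 (SE 0.90), Tmem43 at -3.85 (SE 0.86), Cenpu at -3.36 (SE 0.85), Bcl2l13 at -1.97 (SE 0.53) and 1700040P09Rik at -4.54 (SE 1.25). No gene passed the threshold in limma (0 of 10762), 256 had an unadjusted p under 0.05, and the lowest adjusted p was 1.0. With each array centred and the letter as a block, 854 had an unadjusted p under 0.05 and the lowest adjusted p was 0.0997, for Pgam1 and Phgdh. Centred Phgdh values averaged -0.37 ± 0.48 (SD, n = 3) in WT 0GH, -0.23 ± 0.47 in WT 1GH, 2.15 ± 0.38 in NLS 0GH and 1.67 ± 0.50 in NLS 1GH. Those of Mybbp1a averaged 0.34 ± 0.24, 0.12 ± 0.23, 1.79 ± 0.63 and 1.56 ± 0.18 in the same order. For Pgam1, Phgdh, Eif5a and Mybbp1a, all 6 NLS arrays lay above all 6 WT arrays.

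**Figure D3:**
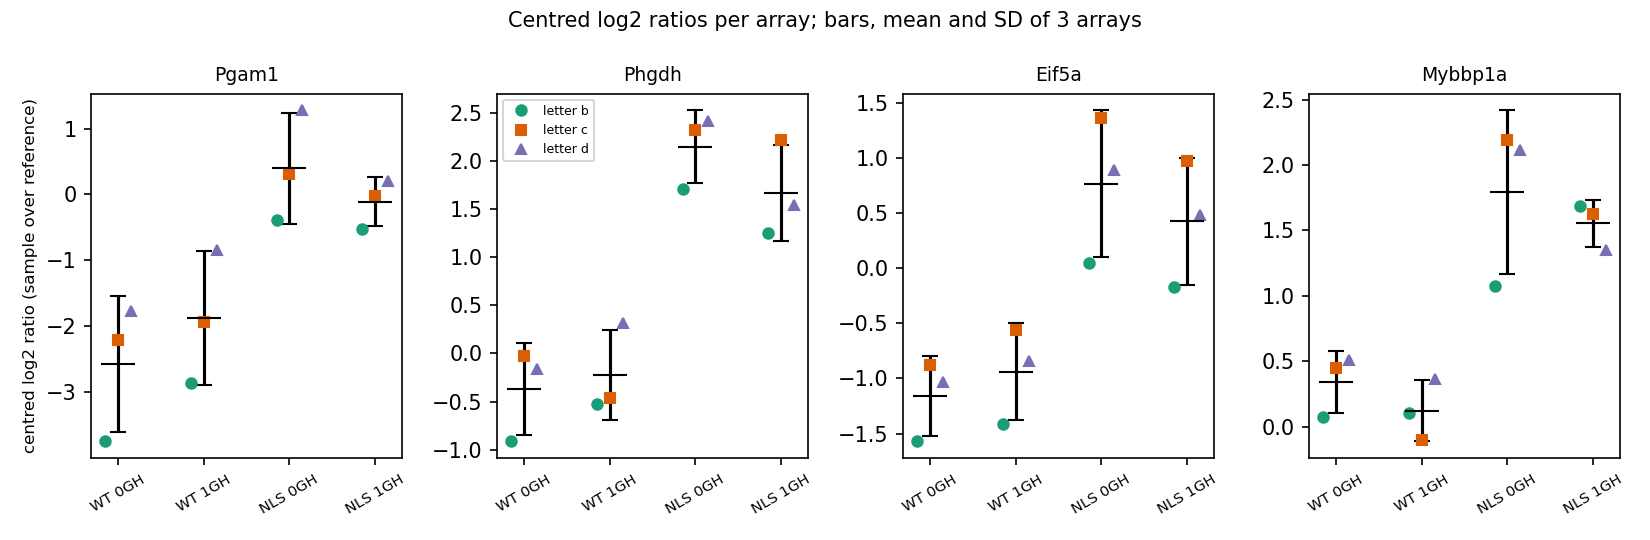
Centred log2 ratio of single genes on each of the 12 arrays, by receptor form, GH number and replicate letter, with the mean of each group of 3. Phgdh averages 2.15 and 1.67 in the NLS groups against -0.37 and -0.23 in the WT groups.

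The remaining lists did not pass the camera test in the averaged comparison. There the list mean was 0.21 for GH and STAT5 target genes (adjusted p = 0.573), 0.04 for immediate early genes (0.870), -0.12 for DNA replication genes (0.870), -0.21 for G2/M and mitosis genes (0.364), 0.01 for apoptosis genes (0.981) and -0.03 for adhesion and cytoskeleton genes (0.954). It was 0.39 for heat shock and unfolded protein response genes (0.0827), 0.18 for interferon response genes (0.573), 0.06 for p53 targets (0.878) and 0.04 for ribosomal protein genes (0.364). Among the marker lists it was -0.16 for B lymphoid (0.597), 0.04 for mast cell and basophil (0.981), -0.11 for myeloid (0.597), 0.09 for T lymphoid (0.878), -0.27 for fibroblast (0.364), 0.49 for hepatocyte (0.246) and 0.00 for epithelial genes (0.954). The embryo-tissue genes were at -0.22 (0.424). Ghr itself was at 1.08 (SE 0.79) in NLS relative to WT, within 2 SE of the shift. Its centred means were -0.24 ± 0.75 (SD, n = 3) in WT 0GH, -0.45 ± 0.62 in WT 1GH, 0.66 ± 1.59 in NLS 0GH and 0.74 ± 1.18 in NLS 1GH. These SDs do not use the pairing by letter. Averaged over both GH numbers, Ghr was higher in NLS arrays in each letter, though it did not pass the threshold.

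The comparison of 1GH with 0GH in WT samples asks what differs between the GH numbers with the wild-type receptor. No list and no gene passed. Cish was at 0.46 (SE 1.01), Socs2, another STAT5-induced inhibitor, at -0.57 (SE 1.14), Pim1, a survival kinase, at 2.90 (SE 1.87), Id1 at 0.59 (SE 0.78), Birc5 at -0.20 (SE 1.14), Mybbp1a at -0.25 (SE 0.67) and Fxyd5 at -0.15 (SE 1.21), so each lay within 2 SE of the shift. The GH and STAT5 target list had a mean of 0.03 (adjusted p = 0.992). These means cover letters that differed in sign: the centred list mean was 0.20 in b, 0.78 in c and -0.77 in d, and the centred difference of Cish was 1.30, 2.44 and -2.25. The value of Pim1 rested on the WT 0GH array of letter c, where it lay at -7.25 after centring, and without that array the difference was 0.06 instead of 2.67, both before subtraction of the shift. In limma 0 of 10762 passed and 159 had an unadjusted p under 0.05, 31 of them higher, at a median shift of -0.23. The smallest p-values belonged to Rtca at 5.05 (SE 1.28), Gbp2 at 3.76 (SE 0.94), Blm, a DNA helicase, at 3.19 (SE 1.0), Rtf2 at 3.21 (SE 1.05) and Hnrnph1 at 2.21 (SE 0.72), and, among lower genes, to Psmd7 at -3.99 (SE 0.88), Cacul1 at -7.71 (SE 1.73), Ktn1 at -4.22 (SE 1.10), Ank3 at -2.85 (SE 0.81) and U2af1, a splicing factor, at -1.86 (SE 0.58). Rtca and Gbp2 were also among the higher genes of NLS against WT at 0GH, which uses the same WT 0GH arrays. Psmd7 and Cacul1 were among those at 1GH, which uses the same WT 1GH arrays. The interaction uses all of these arrays, so a gene named in several comparisons is not a separate result in each.

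In NLS samples the same comparison gave Cish at 0.18 (SE 1.01), Socs2 at -0.40 (SE 1.14), Pim1 at 0.26 (SE 1.87), Id1 at 0.40 (SE 0.78), Birc5, an inhibitor of apoptosis, at -1.49 (SE 1.14), Mybbp1a at -0.20 (SE 0.67) and Fxyd5 at -0.60 (SE 1.21). The GH and STAT5 target list had a mean of -0.09 (adjusted p = 0.921), with centred means of -0.36 in b, 0.04 in c and -0.06 in d. No list passed, and in limma 0 of 10762 genes passed with 234 at an unadjusted p under 0.05, 213 of them higher, at a median shift of 0.27. Adjusted over the list alone, 1 of 24 immediate early genes passed, Maff, a small Maf transcription factor, at 4.54 (SE 1.18) relative to the shift. Its p-value is that of the difference before subtraction of the shift of 0.27, and passing after subtraction was not tested. Other small p-values belonged to 4921528I07Rik at 4.96 (SE 1.05), Snhg7 at 3.61 (SE 0.92), Gphn at 3.27 (SE 0.85) and Dlat at 3.73 (SE 0.96), and, among lower genes, to Mrrf at -3.68 (SE 1.07), Tbc1d9 at -4.63 (SE 1.49), Tbx5 at -4.51 (SE 1.46), Cd180 at -3.15 (SE 1.08) and Dcps at -3.13 (SE 1.08). Averaged over both receptors, no list passed camera, and in limma 0 of 10762 genes passed with 142 at an unadjusted p under 0.05, at a median shift of 0.02. The smallest p-values of that average belonged to Blm at 2.77 (SE 0.71), Med8 at 1.86 (SE 0.50), 4921528I07Rik at 2.78 (SE 0.74), Tmem167b at 2.11 (SE 0.59) and Dlat at 2.44 (SE 0.68), and to Cacul1 at -5.27 (SE 1.22), Tbx5 at -3.09 (SE 1.03), Btk at -2.65 (SE 0.89), 2810408I11Rik at -2.05 (SE 0.70) and Zfp219 at -2.71 (SE 0.94). Of the genes named in advance, Socs1, Socs3 and Myc lacked values on some arrays, Bcl6 on all 12, and Osm had 0 spots, so none of these 5 was tested.

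Whether the GH difference itself differs between the receptor forms was tested as an interaction. Ribosomal protein genes differed relative to the other genes: their 1GH minus 0GH difference was 0.29 above the shift in WT arrays, with 42 of 54 genes above it, and -0.28 relative to the shift in NLS arrays, with 46 of 54 below it. Before subtraction of the shift the list means were 0.05 and -0.01, and the interaction was -0.06, so the difference lies in the position of this list against the median of all genes, which itself moved by -0.23 and 0.27. The interaction of this list was -0.58, with 50 of 54 genes below the shift (camera adjusted p = 0.0255, or 0.0086 with the letter as a block). With an estimated correlation the adjusted p was 0.997, and the exact permutation p was 0.0185, or 0.347 adjusted over the 25 lists. Rps23 was at -2.69 (SE 1.60) and Rps19 at -3.54 (SE 2.54), while Rps6 was at 0.86 (SE 1.04) and Rpl22 at 0.89 (SE 1.69). By letter the interaction was -0.16 in b, -0.68 in c and -1.09 in d, and the adjusted p was 0.00372 without letter b, 0.233 without c and 0.696 without d. Taken alone, the differences in WT and NLS arrays did not pass (adjusted p = 0.223 and 0.160), and with each array centred and the letter as a block they did (0.00258 and 0.000786). With an estimated correlation in that fit, the adjusted p was 0.882 for each. No gene passed the interaction in limma (0 of 10762), and 214 had an unadjusted p under 0.05, 200 of them higher, at a median shift of 0.52. The smallest p-values belonged to 4930533K18Rik at 5.05 (SE 1.32), Psmd7 at 4.59 (SE 1.24), Amz2 at 5.56 (SE 1.59), Prss22 at 4.68 (SE 1.37) and Apbb2 at 7.19 (SE 2.06), and to Rtca at -5.82 (SE 1.81), Mrrf at -4.86 (SE 1.51), Rtf2 at -4.18 (SE 1.49), Poc5 at -4.09 (SE 1.59) and Tbc1d9 at -5.27 (SE 2.11).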

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

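The tests of both patterns, the split count of the receptor average and the relabelling within letters were chosen only after the results were seen. The exception is the estimated correlation without centring for the ribosomal protein interaction, which was planned as an alternative.

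For ribosomal protein genes the difference between the GH numbers differed between WT and NLS arrays by the interaction test, at -0.58 relative to the shift and -0.06 before its subtraction, while neither difference passed on its own. A single array does not account for it with centring and the block, where the highest adjusted p with one array left out was 0.00177. Without centring and block, 8 of 12 such fits gave an adjusted p of 0.05 or more (range 0.000562 to 0.225), with 0.225 without NLS 0GH c, 0.183 without WT 1GH c, 0.0988 without NLS 1GH b, 0.189 without WT 0GH b, and 0.0694, 0.0555, 0.0666 and 0.139 without NLS 0GH, NLS 1GH, WT 0GH and WT 1GH of letter d. Set against genes of matched mean log ratio, the list gave an exact permutation p of 0.0556. A scale difference between arrays therefore stays open, although the matched genes themselves were at -0.00417 against -0.64 for the list. Noise shared by these spots also stays open, since the estimated correlation gave an adjusted p of 0.997, or 0.882 with centring and the block. Before subtraction of the shift the list was at 0.05 in WT and -0.01 in NLS arrays, while the median of all genes moved by -0.23 and 0.27. The scaling of the arrays, or a receptor form that alters the response of these genes to GH relative to the others, may be involved, and neither was tested.

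Higher levels of 5 lists in NLS arrays (ribosome biogenesis, nuclear transport, glycolysis, oxidative phosphorylation, cholesterol synthesis) were weighed as the other pattern, for which noise shared by the spots of a list stays open: an estimated correlation gave an adjusted p of 0.991 for all 5 (0.119 to 0.218 with centring and the block), though the exact permutation of the list means gave 0.0331 after adjustment. A scale difference that depends on the ratio is argued against by an exact permutation p of at most 0.0463 against matched genes. With green dye incorporation as a linear covariate, the smallest share of a list shift kept was 0.981. That incorporation was nowhere higher in the NLS array than in the WT array of the same letter and GH number. The widest gap was 12.8 against 19.2 bases per dye molecule at 1GH in letter c. Since it follows the receptor form, the covariate cannot decide, and green dye incorporation stays open. Dye bias that grows with brightness stays open, since brightness was not measured here and the lists were set only against ribosomal protein genes (highest exact p 0.0278 for 4 lists, 0.0741 for nuclear transport). Chance relabelling of receptor within letters, in a fit with centring and the block where the erythroid markers pass as well, gave as many lists as the real 6 in 3 of 100 assignments, the real one included (highest other 6). A difference caused by the receptor form, or one between separately derived cell lines carrying each form, may explain the lists, and the design does not separate these.

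The number of genes at an unadjusted p under 0.05 was compared with that of other splits of the same arrays. These splits ignore the replicate letters and use the fit without centring or block. In it, chance cannot be excluded for the averaged comparisons: 84 of 100 splits gave as many as the 142 of the GH average (highest other 3887), 72 of 100 as many as the 214 of the interaction (highest other 3887) and 59 of 100 as many as the 256 of the receptor average (highest other 4099). Splits with several times the real count point to a structure of the samples other than the groups. The letters differ in the mean of their array medians as deposited, at -0.557 in b, 0.638 in c and -0.667 in d, and this fit keeps such offsets. The real groups are balanced over the letters and these splits need not be, so the shares cannot decide on chance. The comparisons of 3 against 3 arrays have 10 splits, too few for a share under 0.05. There, 9 gave as many as the 159 of GH in WT (highest other 1261), 6 as many as the 234 of GH in NLS (highest other 1454), 7 as many as the 239 of the receptor at 0GH (highest other 2238) and 7 as many as the 234 of the receptor at 1GH (highest other 852).

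With centring and the letter as a block, labels were also reassigned within letters, in a fit of 6 arrays against 6. Chance relabelling within letters gave as many genes at an unadjusted p under 0.05 as the 913 of the receptor grouping in 1 of 100 assignments, the real one (highest other 738, median 439). That is the smallest share this test can give, in a fit chosen after the data were seen. The test also takes the arrays of a letter as exchangeable. Under that assumption chance is argued against for that count but not excluded. For the GH grouping 44 of 100 gave as many as its 448, and for the interaction grouping 84 of 100 gave as many as its 365 (highest other 913 for each), so chance cannot be excluded there either. No single gene passed in limma in the fits with centring and block (0 of 10762, lowest adjusted p 0.0997 for the receptor average).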

How the results depend on the processing

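The fits with centring and the replicate block together, with or without array weights, and all tests of the averaged receptor comparison were chosen after the data were seen. No gene passed in any comparison under any of the 22 to 27 alternatives run for each, and the lowest adjusted p was 0.345 for GH in WT, 0.155 for GH in NLS, 0.386 for the GH average, 0.140 for the interaction, 0.148 and 0.219 for the receptor at 0GH and 1GH, and 0.0633 for the receptor average. The 5 list calls became 0 with an estimated correlation, 9 with centring, 9 with the replicate block, 10 with both, 11 with array weights added, 0 with both and an estimated correlation, and 0 to 2 with one letter left out (2 without b, 0 without c, 2 without d). The same 5 calls were kept with centring, the block, both, and array weights. With an estimated correlation, and then with centring and block added, the adjusted p was 0.997 and 0.882 for the ribosomal protein interaction (0.00372 to 0.696 without one letter), 0.997 and 0.693 for ribosome biogenesis at 0GH (0.0015 to 0.137), 0.997 and 0.882 for ribosomal protein genes at 0GH (0.102 to 0.329), 0.997 and 0.693 for glycolysis at 0GH (0.0259 to 0.636) and 0.997 and 0.693 for ribosome biogenesis at 1GH (0.0183 to 0.4002). In the receptor average it was 0.991 and 0.119 for ribosome biogenesis (4.25e-06 to 0.0122), 0.991 and 0.119 for nuclear transport (0.00401 to 0.145), 0.991 and 0.218 for glycolysis (0.0106 to 0.0395), 0.991 and 0.128 for oxidative phosphorylation (0.00401 to 0.145) and 0.991 and 0.128 for cholesterol synthesis (0.0183 to 0.0628). Lists that passed only under alternatives follow, with centring, block, both, and array weights where they passed. None of them passed with an estimated correlation, where the adjusted p with centring and block was 0.693 to 0.893, or 0.176 for erythroid markers. Ribosomal protein genes for GH in WT gave 0.0159, 0.00258 with both and 0.001999 with weights (0.102 to 0.971 without one letter). For GH in NLS they gave 0.00367, 0.000786 and 3.77e-06 (0.0815 to 0.696). At 1GH they gave 0.0278 with both and 0.00389 with weights (0.157 to 0.990), and their direction reversed without replicate d (0.990). Oxidative phosphorylation at 0GH gave 0.00841, 0.0238, 0.00143 and 0.000857 (0.108 to 0.507) and at 1GH 0.0415 with the block (0.329 to 0.909). Nuclear transport at 1GH gave 0.00403, 0.0086, 0.00348 and 0.00389 (0.102 to 0.434), glycolysis at 1GH 0.0238 with the block (0.173 to 0.909), and erythroid markers in the receptor average 0.0473, 0.0382, 0.0135 and 0.00529 (0.17 to 0.465). Leaving out a letter also removes 4 of the 12 arrays; otherwise the cause was not tested. Of 4195 values of named genes under alternatives, 4051 moved by less than their SE and 144 by more, with 0 past the threshold. The replicate block, fixed or random, the robust prior and the compared groups alone cannot move a difference in this balanced design. Their agreement was therefore fixed in advance and shows no stability. Leaving out letter b, c or d moved 38, 17 and 25 values. Signal over background is not given in the sources used here, so its limit on dim spots was not measured.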

Other observations

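The tests of separation between the receptor forms and of immediate early genes were chosen only after the results were seen.

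More genes separated the receptor forms in every letter than relabelling within letters gave. With each array centred, both NLS arrays lay on the same side of both WT arrays in all 3 letters for 302 of 10762 features. Of these, 205 were higher and 97 lower. If the arrays of a letter are exchangeable, 0.926% or 99.7 would be expected. The labels do not say whether the 0GH and 1GH arrays of one receptor form and letter share a culture. If they do, more would be expected, by an amount not measured here. Complete separation had first been noticed in Pgam1, Phgdh, Eif5a and Mybbp1a. Chance relabelling of the receptor within letters gave as many in 1 of 108 assignments, the real one, with 250 as the highest other and 87 as the median, and the arrays grouped by GH number gave 82. Genes named here were picked after their values were seen, and their values and SE come from the fit with centring and the block, whose SE are smaller than those of the fit without them. They include the nucleolar genes Nhp2 at 1.28 (SE 0.23), Nifk at 1.54 (SE 0.30) and Nop58 at 1.07 (SE 0.24), the chaperonin subunits Tcp1 at 0.88 (SE 0.21) and Cct6a at 1.03 (SE 0.23), the nucleotide kinase Nme1 at 1.78 (SE 0.29), the immunophilins Fkbp1a at 1.31 (SE 0.22), Fkbp3 at 1.17 (SE 0.23) and Fkbp4 at 1.04 (SE 0.22), and the serum-induced kinase Sgk1 at 1.27 (SE 0.28). Lower in NLS arrays were the cyclin gene Ccnd3 at -1.10 (SE 0.24), the actin-severing gene Gsn at -1.63 (SE 0.31) and Hba-a1 at -1.38 (SE 0.29). The receptor form, or cell lines derived separately for each form, may underlie these differences, and the 108 assignments do not separate these.

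Immediate early genes, which respond first to many stimuli, had a list mean of 0.37 in 1GH against 0GH arrays, averaged over both receptors, and 0.43, 0.27 and 0.40 by letter. Of 24 genes 15 lay above the shift and the median was 0.10, so a few genes carry the mean. Maff was at 2.67 (SE 0.84), Nr4a1 at 1.64 (SE 1.13), Zfp36 at 1.43 (SE 1.23) and Btg1 at 0.92 (SE 0.80). Relabelling the GH number within letters gave an exact p of 0.00926, the smallest that 216 assignments can give. Over the 25 lists it was 0.231, and the camera adjusted p was 0.309, so the list did not pass either correction. An early response to the hormone is a candidate explanation that these values do not establish.

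Presence of a value was also compared. A value on at least 5 of 6 arrays of one receptor form and on at most 1 of 6 of the other was found for 42 spots, 16 for NLS and 26 for WT. Relabelling within letters gave as many in 39 of 108 assignments (highest other 88, median 36), so chance cannot be excluded.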
